A study of Mus musculus with 2 samples.

How the data were processed

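RNA from abdominal cavity macrophages, 1 WT and 1 Trem2 knockout library, both after TGF-β1 for 24 h, was made into strand-marked (dUTP) libraries and sequenced on an Illumina instrument, per the labels' protocols. The values the authors deposited are FPKM per gene, per the file headers, in 1 table with 1 column per library, and the genome build mm10 is named in the submitters' processing notes. The aligner, the quantifier, the annotation and any scaling between libraries beyond that for library size are not given in the sources used here. The table holds 11349 protein-coding genes. Each reached 0.501 FPKM or more in at least 1 library, so genes low in both were not analysed here. Groups were taken from the sample titles. The genotype label of the knockout sample reads knockdown where its title marks a full loss, and the title was followed. Both columns matched a sample by name.

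Gene IDs were compared with GENCODE release M21. With version and position 9914 of 11349 IDs matched, and without the version 11333. In 99.99% of 7955 genes with several transcripts the FPKM times the gene's merged exon length was a number with 6 decimals in both libraries, against 20.4% with a length 1 base longer, as a length-weighted sum over transcripts would give. Depth was estimated from single-transcript genes with low values. FPKM times merged exon length fell on whole multiples of a step, within 0.1 steps, in 63.4% of 123 WT values and 71.5% of 186 knockout values, where chance gives 20.0%. Low values piled up just under 300 and 600 steps, in 2 of 5 WT values and 8 of 15 knockout values up to 2 fragments, and 300 steps were taken as 1 fragment. That gives 13.5 M fragments in WT and 12.4 M in the knockout behind the scaling for library size, of which 10.1 M and 9.11 M fall in the 9914 listed genes with a length. In the WT library 9.67% of these genes have under 50 fragments and in the knockout 16.4%. These are estimates, since the deposited values hold no read counts, and they were used for intervals only. The interval is the exact Clopper-Pearson 95% interval of the knockout share of a gene's fragments, turned into a ratio of FPKM. It covers counting error only and was left out for genes without a matched length.

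The fold change is log2((knockout FPKM + 1)/(WT FPKM + 1)), which understates the change of low genes, among genes with a mean of 1 FPKM or more over both libraries. Genes were counted by size alone, at 2-fold or more, because 1 library per group allows no test. Gene lists were fixed before the data were examined, 49 in all, of which 40 had 5 or more measured members. For each, the median fold change was set against 10000 random lists of the same size matched on mean FPKM in 20 equal bins, and a list was said to stand apart below percentile 2.5 or above 97.5. This describes the 2 libraries and genes are not replicates. A symbol with 2 gene IDs was represented by the ID with the higher mean FPKM. Such symbols numbered 10.

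Genes named in the text were chosen by a rule also fixed before the data were examined. It takes fixed genes, among them Trem2, Tyrobp, Hspa1a, Hspa1b, Akt1 and Akt2, then the 12 genes with the highest and the 12 with the lowest fold change at a mean of 10 FPKM or more, leaving out predicted genes and antigen receptor segments. From each list it takes up to 4 members with the largest absolute fold change at a mean of 1 FPKM or more, and all members where fewer than 5 were measured. Genes named outside it are said to be so, and some genes that the rule takes are not reported here.

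The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter and a mean of 5 FPKM or more, rescaling to a common total, scaling by the median of ratios over genes at 1 FPKM or more in both libraries, a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed on each side), thresholds of 1.5-fold and 4-fold, and list means. Removal of lowess trends with GC content and transcript length, counts from the counting intervals, and list member counts relative to the median of all genes were added after seeing the data. The steps were tested on simulated fragments for the comparison of knockout with WT, with 8668 genes of which 200 were changed. The 2-fold rule recovered 86.6% of genes changed 3-fold and 95.5% of those changed 6-fold, passed 0% of those changed 1.5-fold and 0% of unchanged genes, and 95.4% of counting intervals held the true ratio. Of 200 unshifted lists 6% fell outside the percentiles. The simulated libraries shared the same mean for each unchanged gene and differed by counting error and the planted changes only. These shares therefore do not measure false calls from variation between cultures or animals. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.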

Results

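Gene expression was measured by RNA sequencing in mouse macrophages, phagocytic immune cells, taken as primary cells from the abdominal cavity and kept with TGF-β1, a growth factor that drives wound repair and scarring, for 24 h. There were 2 groups of 1 library each, wild-type (WT) cells and cells from knockouts of Trem2, a lipid-sensing receptor of macrophages that signals through the adaptor Tyrobp. The series asks which genes differ between knockout and WT macrophages, as background to work on kidney fibrosis and the exosomes these cells release, and its title names Hspa1b and AKT. With 1 library per group no difference has a replicate check, so the values describe these 2 libraries and genes are picked out by a fixed rule of size. The table lists 11349 protein-coding genes with values as FPKM, fragment counts scaled for the length of the gene and the size of the library. From the steps between low values, the depth is estimated at 13.5 M fragments for the WT library and 12.4 M for the knockout library, with a median of 375 and 251 fragments per listed gene. Intervals given below are exact (Clopper-Pearson) 95% intervals of the ratio between the libraries, and cover counting error only.

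Trem2 itself was at 135 FPKM in the WT library and 13.7 FPKM in the knockout library, 9.91-fold lower (interval 9.23 to 10.7), which leaves 10.1% of the WT value. The gene lies on chromosome 17 from 48346401 to 48354147 (mm10, + strand, ENSMUSG00000023992.14), and a value per gene does not show which exons the remaining fragments came from. Its adaptor Tyrobp was at 1021 FPKM in WT and 1194 FPKM in the knockout. On the log2(FPKM + 1) scale, genes standing highest in the knockout library against WT, at a mean of 10 FPKM or more, included heat-shock genes (Hspa1b, Hspa1a), contractile and TGF-β response genes (Tagln, Acta2, Ctgf), MHC genes (H2-Q6, H2-Q7, H2-Eb1, H2-Aa, H2-Ab1) and the acute-phase protein Orm1. The 12 standing lowest were Serpinb2, Cxcl5, mt-Nd3, C5ar1, Dusp6, Ccl2, Dhrs9, Trem2, Trib3, Fos, mt-Co2 and Evi2.

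Among the 9962 genes with a mean of 1 FPKM or more, 347 were at least 2-fold higher in the knockout library and 1364 at least 2-fold lower on the log2(FPKM + 1) scale. The median log2 fold change of all these genes was -0.31, and -0.24 for those with a mean of 5 FPKM or more. The shift varied with expression level, since random lists matched on it had medians from -0.37 to 0.23. With the median of the ratios set to 1 the counts were 743 higher and 814 lower, with a trimmed mean of log ratios set to 0 they were 750 and 814, and after rescaling both libraries to the same total they were 335 and 2439. The share of higher genes among all those past 2-fold was thus 20.3% as deposited, 47.7% and 48.0% under the first 2 scalings and 12.1% under the third. Fth1, the heavy chain of the iron store ferritin, alone made up 5.53% of the summed FPKM in WT and 11.2% in the knockout. List medians are given below relative to the median of all genes, their percentiles among lists matched on expression, and counts of list members both as deposited and relative to it. In these counts higher and lower mean by 2-fold or more.

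**Figure D1:**
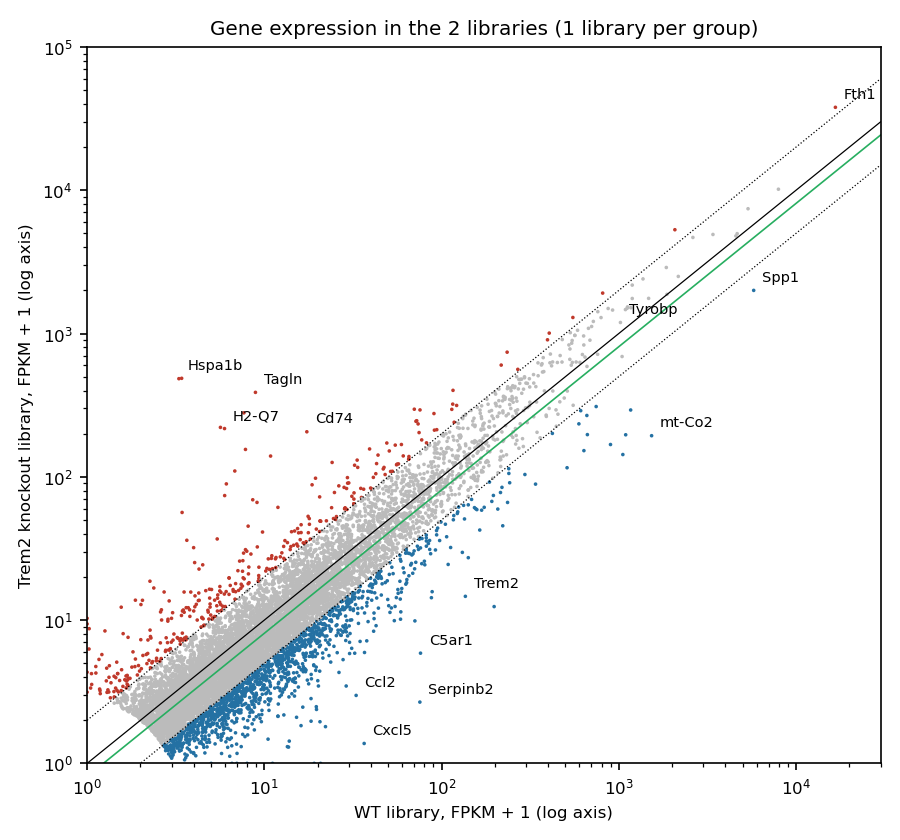
FPKM + 1 of each gene with a mean of 1 FPKM or more in the WT library (x axis, log scale) and the Trem2 knockout library (y axis, log scale), 1 point per gene. Red points are the 347 genes at least 2-fold higher and blue points the 1364 at least 2-fold lower in the knockout; the black line marks equal values, dotted lines 2-fold differences and the green line the median of all genes at -0.31 (log2).

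Hspa1a and Hspa1b, a pair of near-identical genes for the stress-inducible chaperone HSP70, stood furthest apart between the libraries on the log2(FPKM + 1) scale, among genes with a mean of 1 FPKM or more. Hspa1b was at 2.30 FPKM in WT and 483 FPKM in the knockout, 210-fold higher (interval 170.0 to 262), and Hspa1a at 2.42 and 486 FPKM, 201-fold higher (interval 164 to 247). Because reads can be assigned to either copy, their sum is the safer value, 4.71 FPKM in WT and 969 FPKM in the knockout. Both lie on chromosome 17 (mm10), Hspa1b from 34956436 to 34959238 and Hspa1a from 34969190 to 34972156, next to Hspa1l, which was at 0.873 and 12.8 FPKM. Of the 27 measured heat-shock and cytosolic chaperone genes, 6 were at least 2-fold higher and 0 lower, or 11 higher relative to the median of all genes. Hspb1, a small heat-shock protein, went from 25.3 to 85.5 FPKM between WT and knockout. The list's median lay 0.84 above that of all genes on the log2 scale, at percentile 99.99 among 10000 random lists matched on expression.

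Akt1 and Akt2, kinases that relay growth-factor signals, showed smaller differences. Akt1 was at 63.4 FPKM in WT and 60.5 FPKM in the knockout. At the deposited scaling this difference lay within counting error (ratio of WT to knockout 1.05, interval 0.997 to 1.10). The interval takes that scaling as exact. The log2 fold change of Akt1 was -0.07 as deposited and 0.25 with the median of ratios set to 1, so its direction depends on the scaling. Akt2 was 2.02-fold higher in the knockout (6.65 and 13.4 FPKM, interval 1.83 to 2.22). On the log2(FPKM + 1) scale Akt2 stood at 0.91, under 2-fold, and passed 2-fold relative to the median of all genes at 1.22. Of 26 measured PI3K-AKT-mTOR components 3 were at least 2-fold lower, Pik3r2, Pik3cg and Pik3ap1, and 0 higher, but 1 lower and 2 higher relative to the median of all genes. The list stood at percentile 91.2, within the range of random lists.

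Genes of antigen presentation by MHC class II, by which cells show peptides to helper T cells, were at least 2-fold higher in the knockout library in 6 of 7 measured members. H2-Eb1 was at 5.81 FPKM in WT and 109 FPKM in the knockout, H2-Aa at 5.11 and 88.3 FPKM, H2-Ab1 at 9.85 and 139 FPKM, and Cd74, the invariant chain, at 16.4 and 205 FPKM. Of the 12 class I genes, 8 were at least 2-fold higher and none lower, or 9 higher relative to the median of all genes. H2-Q6 was at 4.65 and 220 FPKM, H2-Q7 at 4.96 and 216 FPKM, H2-T22 at 31.3 and 119 FPKM, and H2-Q4 at 32.7 and 115 FPKM. H2-Q6 and H2-Q7 are close relatives whose reads can be split between copies. The class II median lay 3.88 and the class I median 1.81 above all genes, each above every one of the 10000 random lists. Apart from Cd74 on chromosome 18 and B2m on chromosome 2, the listed members of both lists lie on chromosome 17. Ciita, which the class II list also names, is not among the listed genes.

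**Figure D2:**
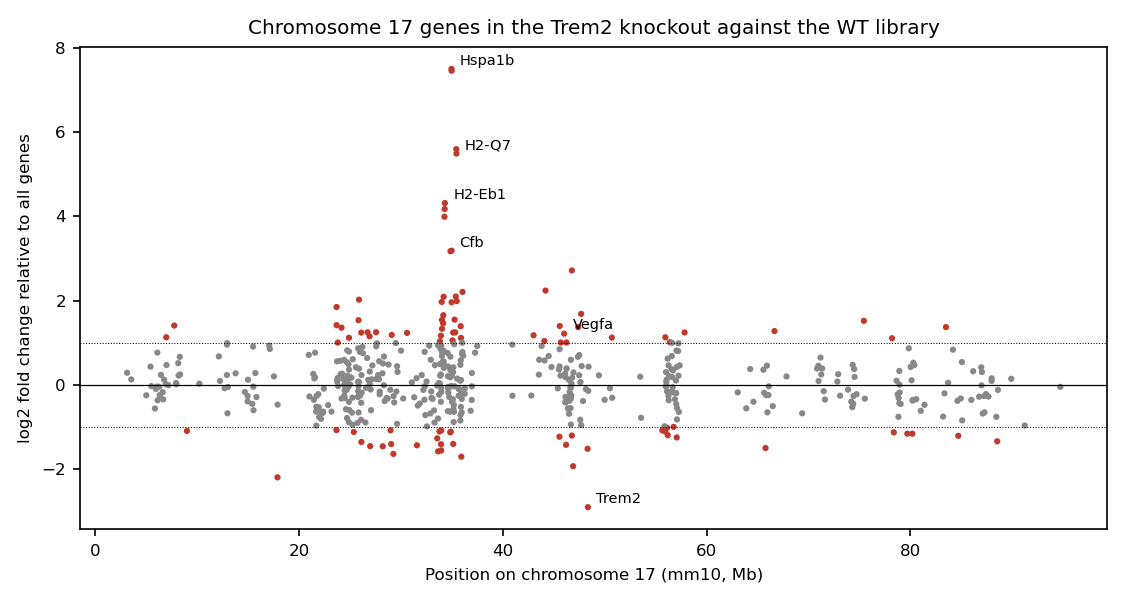
Log2 fold change of the knockout against the WT library relative to the median of all genes (y axis) for each chromosome 17 gene with a mean of 1 FPKM or more, by position in Mb (x axis, mm10); red points are at least 2-fold away and dotted lines mark 2-fold. Hspa1a at 7.46, H2-Q7 at 5.49 and H2-Eb1 at 4.32 are among the highest points, and Trem2 at -2.91 is the lowest.

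Contractile and matrix genes, the products of activated scar-forming cells, were higher in the knockout library as a group. Tagln, an actin-binding protein of smooth muscle, was at 7.91 FPKM in WT and 388 FPKM in the knockout, 49.0-fold higher (interval 42.8 to 56.4), and Acta2, smooth muscle actin, at 6.67 and 279 FPKM. Col1a1 was at 48.1 and 171 FPKM and Col5a2 at 6.96 and 29.3 FPKM. Of 29 measured matrix and fibrosis genes, 9 were at least 2-fold higher and 1 lower, Spp1 (osteopontin), at 5773 FPKM in WT and 2000 FPKM in the knockout. Relative to the median of all genes 12 were higher and 1 lower, and the list's median lay 0.81 above all genes, above every random list. Among fibroblast and pericyte markers, 5 of which are also in that list, 3 of 10 were higher and 2 lower, or 5 and 1 relative to all genes, with a median 0.77 above all genes at percentile 99.3. Within it Pdgfra, the fibroblast PDGF receptor, went the other way (29.3 and 6.0 FPKM). The mean of the list in place of its median lay within the range of random lists, at percentile 96.4.

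TGF-β pathway and target genes went both ways, with 3 of 31 higher and 4 lower, or 3 and 3 relative to all genes, at percentile 75.4. Ctgf, a matrix-associated growth factor, was at 2.44 FPKM in WT and 55.4 FPKM in the knockout. The receptor gene Tgfbr1 was at 14.2 FPKM in WT and 1.10 FPKM in the knockout, 12.9-fold lower (interval 10.4 to 16.2), and Id1 at 14.5 and 3.96 FPKM. The mean of this list in place of its median stood apart, at percentile 97.9. Fibrogenic growth factors had 1 of 12 members higher, Pdgfb (1.99 and 5.03 FPKM), and 1 lower, Hgf (2.62 and 0.792 FPKM), or 4 higher and 0 lower relative to all genes. Their median lay 0.47 above all genes at percentile 98.5, a call that ended when genes under a mean of 5 FPKM were left out (percentile 94.1) and when the mean was taken (percentile 95.4). Metalloproteinases and inhibitors went both ways, 5 of 17 higher and 5 lower on either count, at percentile 51.6. That list also holds genes of the plasminogen activator system, Serpinb2 among them. Mmp3 was at 1.60 and 10.4 FPKM, Mmp12 at 235 and 65.3 FPKM, and Serpinb2 at 74.5 and 1.68 FPKM.

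**Figure D3:**
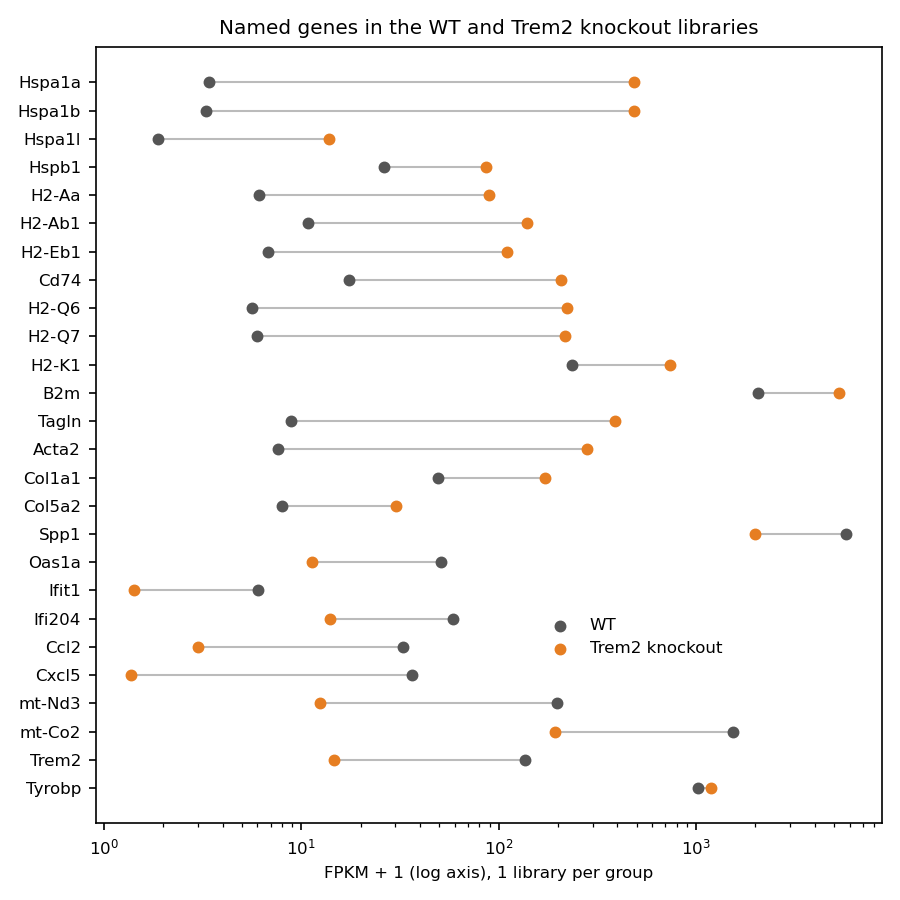
FPKM + 1 (x axis, log scale) of named genes (y axis) in the WT library (dark grey) and the Trem2 knockout library (orange), 1 library per group, with a line joining the 2 values of a gene. Hspa1a, Hspa1b, Tagln and the MHC genes lie to the right in the knockout, and Trem2, Ccl2 and Cxcl5 to the left.

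Of 35 measured genes of the type I interferon response, by which cells resist viruses, 17 were at least 2-fold lower in the knockout library and 0 higher, or 12 lower and 1 higher relative to the median of all genes. Oas1a, which has close relatives that can share its reads, was at 50.2 FPKM in WT and 10.3 FPKM in the knockout, Ifi204 at 57.5 and 13 FPKM, and Ifit1 at 5.07 and 0.414 FPKM. The list's median lay 0.67 below all genes (-0.67), below every random list. Interferon-gamma response genes had 5 of 18 lower and 1 higher, Tap1 of the MHC region, or 2 lower and 1 higher relative to the median of all genes, with a median of -0.18 relative to all genes at percentile 14.8. With no filter on low values that list had 22 members and stood at percentile 1.41.

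Of 16 chemokine genes, which recruit leukocytes, 8 were lower and 2 higher, or 6 lower and 4 higher relative to the median of all genes, and the median was -0.59 relative to all genes, at percentile 0.01. Cxcl5, a neutrophil attractant, was at 35.6 and 0.377 FPKM, and Ccl2, which recruits monocytes, at 32.0 and 1.98 FPKM, 16.1-fold lower (interval 11 to 24.5). Ccl5 went the other way, from 4.42 to 35.8 FPKM. Toll-like receptors and adaptors, which sense microbes, had 7 of 22 lower and 1 higher, or 6 and 1 relative to all genes, with a median of -0.45 at percentile 0.26. Tlr13 was at 87.5 and 14.8 FPKM and the adaptor Myd88 at 21.8 and 5.97 FPKM. Efferocytosis and scavenger receptors, which take up dying cells and lipids, had 8 of 24 lower and 0 higher, or 5 and 0 relative to all genes, with a median of -0.29 at percentile 0.41. Among them were Mrc1 (33.7 and 6.10 FPKM), Cd36 (635 and 151 FPKM) and Msr1 (79.5 and 23.3 FPKM).

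Pan-macrophage identity genes had 6 of 22 members lower and 0 higher, or 4 and 0 relative to all genes, with a median of -0.17 at percentile 0.62. Fcgr1, an antibody receptor, was at 55.9 and 14.4 FPKM, and the transcription factor Maf at 26.0 and 7.53 FPKM. Cytoskeleton and adhesion genes had 10 of 30 lower and 1 higher, or 7 and 1 relative to all genes, with a median of -0.12 at percentile 0.79. Actb, often used as a reference gene, was at 664 and 196 FPKM, and Flna, an actin cross-linker, at 54.6 and 13.4 FPKM. Exosome biogenesis and cargo markers, the group closest to the series' title, had 5 of 30 lower and 0 higher, or 2 lower relative to the median of all genes. Their median was -0.15 relative to all genes at percentile 1.46, and the call ended once trends with GC content and length were removed, with the median itself going from -0.46 to -0.45 over the 29 members that have these measures, at percentile 2.81. Among them were Rab35 (30.8 and 11 FPKM) and Anxa2 (239 and 105 FPKM).

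**Figure D4:**
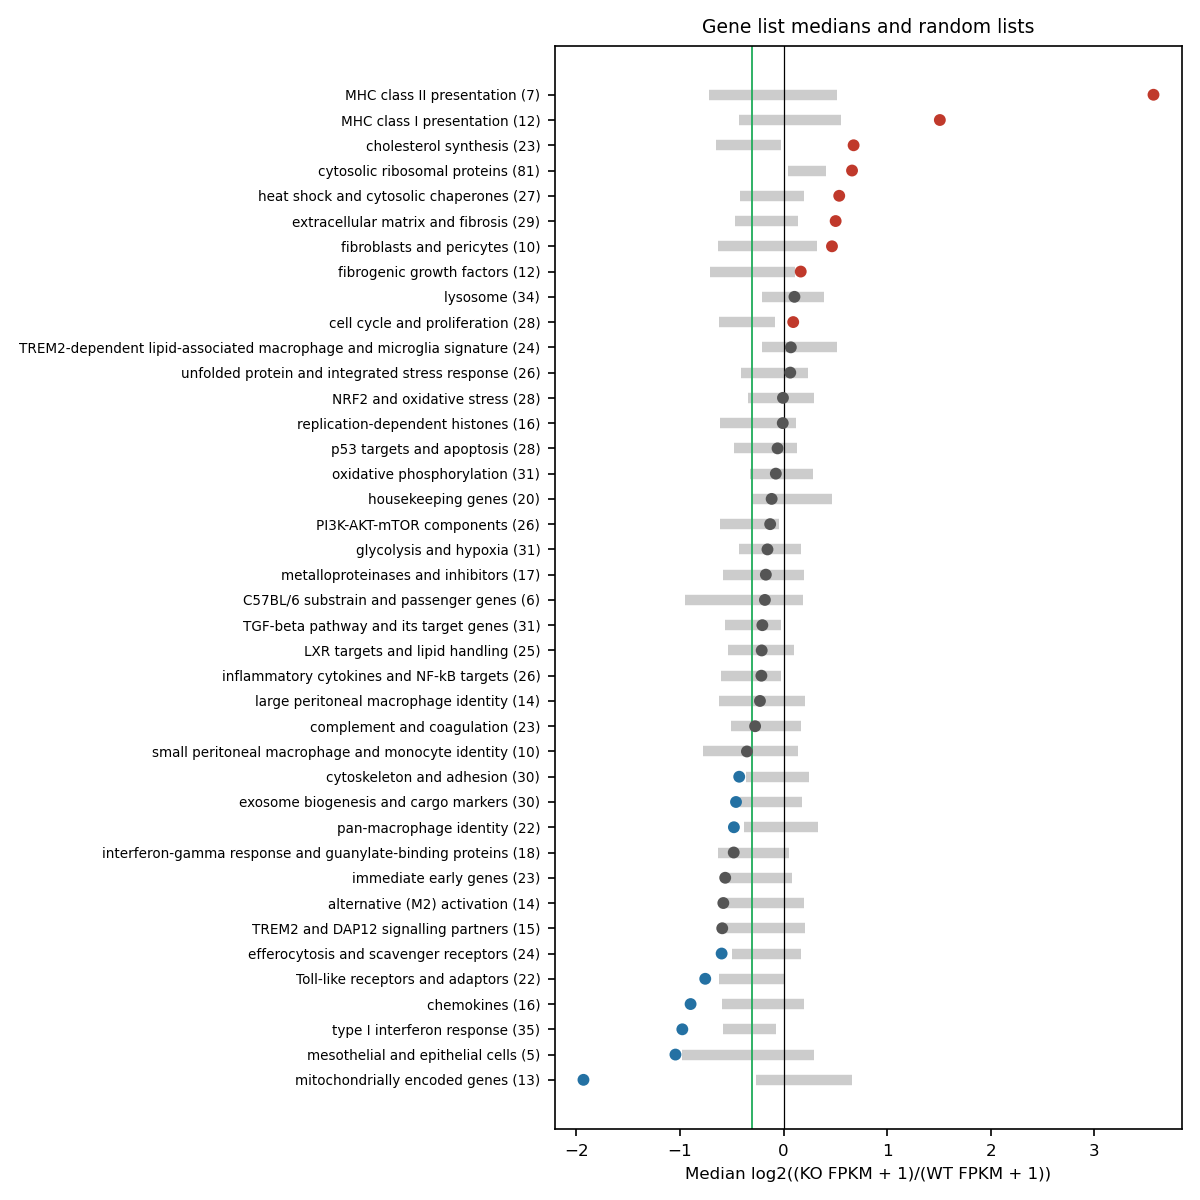
Median log2((KO FPKM + 1)/(WT FPKM + 1)) of each of the 40 gene lists with 5 or more measured members (x axis; member number in brackets on the y axis), with grey bars spanning the central 95% of 10000 random lists matched on expression. Red points lie above and blue points below that span, dark points within it; the green line is the median of all genes at -0.31. MHC class II at 3.57 is highest and mitochondrially encoded genes at -1.93 are lowest.

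Metabolic groups differed in direction. Of 23 cholesterol synthesis genes 7 were at least 2-fold higher and 0 lower, or 10 higher relative to the median of all genes, and their median lay 0.98 above all genes, above every random list. Insig1, a sterol-sensing regulator, was at 8.77 and 40.2 FPKM, and Mvd, an enzyme of the pathway, at 6.64 and 28.4 FPKM. Cytosolic ribosomal protein genes lay 0.97 above all genes as a median of 81, above every random list (0.66 as deposited, where matched random lists had 0.20), although 1 of them, Rps25, was at least 2-fold higher as deposited and 34 relative to the median of all genes. Mitochondrially encoded genes were at least 2-fold lower in 11 of 13 members, or 9 relative to the median of all genes, with a median of -1.63 relative to all genes, below every random list. Of these mt-Nd3 was at 197 and 11.4 FPKM, mt-Co2 at 1532 and 193 FPKM and mt-Cytb at 1054 and 142 FPKM. The nuclear oxidative phosphorylation genes had 1 of 31 lower, Cox5b, and 0 higher, or 1 and 1 relative to all genes, at percentile 35.5.

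Cell cycle genes had 2 of 28 members at least 2-fold lower, Stmn1 (13.4 and 4.32 FPKM) and Pcna (83.3 and 33.3 FPKM), and 0 higher, but 1 lower and 2 higher relative to all genes. Their median lay 0.40 above all genes at percentile 99.95, and the list stayed above random lists after rescaling to the same total, at percentile 99.96, though the median itself, not taken relative to all genes, turned from 0.09 as deposited to -0.018. Over the 6 members with a mean of 5 FPKM or more the median as deposited was -0.75 at percentile 6.07, which ends the call.

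Many markers of other cell types were not listed, and those measured ranged widely in level. The fibroblast markers Col1a1 (48.1 and 171 FPKM) and Pdgfra (29.3 and 6.0 FPKM) were clearly expressed in both libraries. The B cell list had 1 measured member, Cd22, at 8.58 and 9.29 FPKM. Dendritic cell markers had 4, Bst2 (125 and 217 FPKM), Cd24a (59.7 and 41.8 FPKM), Fscn1 (10.5 and 11.8 FPKM) and Batf3 (1.72 and 0.666 FPKM). Of T and NK cell genes Il7r was at 158 and 84.7 FPKM, Thy1 at 0.336 and 3.80 FPKM, Lck at 0.846 and 1.76 FPKM, and Cd28 at 1.48 and 0.684 FPKM. Neutrophil genes were Mmp8 (19.5 and 6.74 FPKM), Csf3r (16.6 and 9.52 FPKM), S100a8 (15.7 and 8.17 FPKM) and Lcn2 (1.52 and 2.0 FPKM). Of mast cell genes Cma1 was at 4.83 and 1.42 FPKM, Tpsb2 at 3.67 and 0.732 FPKM and Cpa3 at 2.40 and 0.518 FPKM. The endothelial genes Vwf and Kdr were at 3.88 and 0.868 FPKM and at 2.04 and 0.545 FPKM. Of 15 erythroid and platelet markers only Pf4 was listed, at 163 and 41.5 FPKM, and it is also in the chemokine list. Mesothelial and epithelial markers, of cells lining the abdominal cavity, were at least 2-fold lower in 3 of 5, or 2 relative to all genes, with a median of -0.74 at percentile 1.63. Krt19 was at 4.74 and 0.172 FPKM and Wt1 at 6.20 and 2.49 FPKM. That call ended with a pseudocount of 0.1 FPKM (percentile 3.83) and with no filter on low values (percentile 3.76). Of the neighbours of Trem2, Foxp4 was at 4.49 and 2.39 FPKM, Nfya at 12.6 and 8.91 FPKM, and Oard1 at 27.6 and 30.1 FPKM. B430306N03Rik, which also lies close to Trem2 and was chosen after its values were seen, was at 12.9 and 2.91 FPKM. The sex-linked list had 0 listed members.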

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

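All alternatives were chosen before the data were examined except the GC and length trends, the counting intervals and the member counts relative to the median of all genes. Trem2 and Hspa1b stayed past 2-fold in their direction under all 7 alternatives run for single genes. Of 140 named genes past 2-fold, 98 stayed past it under all of these they could be computed for, and of 40 named genes within 2-fold, 17 stayed within. Of 18 lists that stood apart, 13 stayed on the same side under all 9 list alternatives. No paired analysis was possible because each group has 1 library.

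Counts of genes depended on the settings. Genes at least 2-fold higher, 347 as reported, numbered 174 with a pseudocount of 5 FPKM, 743 with the median of ratios set to 1, 750 with the trimmed mean, 995 at 1.5-fold and 51 at 4-fold. Genes at least 2-fold lower, 1364 as reported, numbered 2075 with a pseudocount of 0.1 FPKM, 394 with 5 FPKM, 746 at a mean of 5 FPKM or more, 2439 after rescaling to a common total, 814 with either other scaling, 3254 at 1.5-fold and 113 at 4-fold. Counting intervals clear of 2-fold gave 279 higher and 1186 lower, over the 8668 genes with a length. They use the plain FPKM ratio without the pseudocount, so these genes are not a subset of the 347 and 1364. The members of the tested lists at least 2-fold higher numbered 85 as reported and 168 relative to the median of all genes, and the members of the tested lists at least 2-fold lower 160 and 107, a gene in several lists counted in each.

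The cell cycle median, 0.09 as reported, was -0.75 at a mean of 5 FPKM or more with 6 of 28 members left, -0.018 after rescaling and -0.029 as a mean, and stood at percentiles 6.07, 99.96 and 99.4 of random lists. The calls of 4 other lists ended. Mesothelial markers had medians of -1.28 with a pseudocount of 0.1 FPKM and -0.72 with no filter, fibrogenic growth factors had 0.17 at a mean of 5 FPKM or more and 0.062 as a mean, exosome markers had -0.45 without the GC and length trends, and fibroblast markers had 0.31 as a mean. Lists that newly stood apart were alternative (M2) activation (-0.48 with a pseudocount of 5 FPKM, -0.87 at a mean of 5 FPKM or more, -0.71 as a mean), interferon-gamma response (-0.62) and immediate early genes (-0.57) with no filter, and, as means, the unfolded protein and integrated stress response (-0.39) and the TGF-β list (-0.023). Apart from the fewer members left by a filter, the cause was not tested.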

Other observations

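The tests of summed Hspa1a and Hspa1b, of the other heat-shock genes, of B cell and dendritic cell markers, of Cd79a and Cd79b, of interferon genes, of MHC list members on other chromosomes, of fibroblast markers and of the chromosome 17 stretches without further MHC genes and overlapping genes were chosen only after the result was seen. The list of the unfolded protein and integrated stress response had 5 of 26 members lower in the knockout library and 0 higher, or 5 and 1 relative to the median of all genes, at percentile 82.7. Its mean in place of its median, -0.39 against 0.064, stood apart on the low side at percentile 1.80. Chac1 was at 12.5 and 0.308 FPKM in WT and knockout, Trib3 at 28.0 and 2.47 FPKM, Sesn2 at 15.5 and 1.47 FPKM, and Asns, asparagine synthetase, at 49.3 and 11.6 FPKM. Immediate early genes went both ways, with 7 of 23 lower and 3 higher, or 5 and 3 relative to all genes, at percentile 2.74, and stood apart with no filter on low values, at percentile 1.84. Fos was at 18.7 and 1.38 FPKM, Ier2 at 25.4 and 3.31 FPKM, and Maff at 1.05 and 12.8 FPKM. The complement receptors C5ar1 (75.1 and 4.88 FPKM) and C3ar1 (221 and 44.5 FPKM) were lower while complement factor Cfb was higher (8.09 and 65.3 FPKM), in a list with 8 of 23 lower and 3 higher, or 6 and 3 relative to all genes, at percentile 26.0. Of p53 and apoptosis genes 3 of 28 were higher and 5 lower, but 7 higher and 3 lower relative to all genes, at percentile 79.1, among them Gdf15 (23.1 and 125 FPKM), Fas (8.13 and 31.4 FPKM) and Bcl2l1 (17.8 and 4.55 FPKM).

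Lipid-associated macrophage genes that depend on Trem2 did not stand apart as a list, with 2 of 24 higher and 5 lower, or 3 and 4 relative to all genes, at percentile 32.4. Plin2, which coats lipid droplets, was at 510 and 115 FPKM, Cd36 at 635 and 151 FPKM, and Cd52 at 71.5 and 245 FPKM. The partners of Trem2 and Tyrobp had 4 of 15 lower, Plcg2, Ptpn6, Btk and Card9, but 0 relative to all genes, at percentile 2.82. Alternative (M2) activation genes had 6 of 14 lower and 1 higher, or 4 and 2 relative to all genes, at percentile 3.56. That list stood apart on the low side with a pseudocount of 5 FPKM (percentile 1.29), at a mean of 5 FPKM or more (percentile 0.26, with the median going from -0.58 to -0.87) and as a mean (percentile 0.46). Large peritoneal macrophage genes had 4 of 14 lower and 2 higher, or 3 and 3 relative to all genes, at percentile 46.0, with Gata6, the transcription factor of these cells, at 14.0 and 2.67 FPKM. Small peritoneal macrophage and monocyte genes had 2 of 10 lower and 1 higher on either count at percentile 44.1, with Plac8 at 3.92 and 13.2 FPKM. Inflammatory cytokines and NF-kB targets had 2 of 26 lower and 1 higher, Il1a (23.9 and 76.7 FPKM), but 2 lower and 4 higher relative to all genes, at percentile 74.6. Glycolysis and hypoxia genes, with P4ha1 at 53.8 and 165 FPKM, had 4 of 31 higher and 2 lower, or 8 and 1 relative to all genes, at percentile 44.9. Lipid handling genes, with Lpl at 167 and 57.5 FPKM, had 4 of 25 higher and 5 lower, but 4 and 3 relative to all genes, at percentile 52.6. NRF2 targets, with Gpx1 at 89.6 and 275 FPKM, had 3 of 28 higher and 0 lower, or 7 and 0 relative to all genes, at percentile 56.5. Lysosome genes, with Hexa at 550.0 and 1294 FPKM, had 1 of 34 higher and 3 lower, but 3 higher and 0 lower relative to all genes, at percentile 56.8. The remaining lists, replication-dependent histones (1 of 16 higher and 1 lower, or 3 and 0 relative to all genes, percentile 90.0, with reads shared among near-identical copies), housekeeping genes (2 of 20 higher and 1 lower, or 3 and 1, percentile 15.6) and genes that differ between C57BL/6 substrains (0 of 6 higher and 1 lower, but 1 and 0, percentile 74.5), were within the range of random lists too. The substrain genes need not share a direction, so their median cannot show whether the mice differ in background. Among them Ide was at 12.8 and 5.09 FPKM and Wdfy1 at 2.95 and 6.64 FPKM, with Nnt (3.05 and 2.45 FPKM) less far apart. Some genes, chosen after their values were seen, were listed at 0 in 1 library. In the knockout these were Eno1b (19.8 FPKM in WT), Cd300ld5 (18.1 FPKM) and Gvin1 (6.99 FPKM), and in WT Igfbp2 (9.29 FPKM in the knockout). Eno1b and Cd300ld5 have close relatives, which leaves their values uncertain. Whether reads of Gvin1 or Igfbp2 were assigned to other genes was not examined.

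For the height of Hspa1a and Hspa1b, reads moved between the copies would leave their sum alike, but the log2 ratio of the summed FPKM was 7.41, which argues against it. The other 25 members of the heat-shock list lay 0.83 above all genes as a median. The bootstrap interval over members was 0.19 to 1.06, which includes 2-fold but lies far under 7.41. These values argue against a rise of like size across the whole group. As deposited, Hspa1l, Hspb1, Dnajb4 (2.41 and 9.77 FPKM) and Dnajb6 (27.5 and 59.2 FPKM) were at least 2-fold higher. Fkbp4 and Bag3 were lower as deposited but within 2-fold, and relative to all genes they lay at -0.40 and 0.03. Dnajb4, Dnajb6, Fkbp4 and Bag3 were named after their values were seen. Relative to all genes 11 of the 27 list members, Hspa1a and Hspa1b included, were at least 2-fold higher and 0 lower. A smaller response of the group, uneven between members, stays open. A candidate explanation is a stretch of chromosome 17 that differs between the WT and knockout mice, since the sources used here do not say whether these share a background. The WT values are labelled C57 and the knockout values only KO. Around the MHC, at 33 to 37 Mb, 22.6% of 93 genes outside the MHC and heat-shock lists were at least 2-fold away from the median of all genes (percentile 98.4 of random gene sets; 4.26% of runs of as many neighbouring genes on other chromosomes were as high), but 20.7% of 87 without further MHC genes and overlapping genes (percentile 94.65; 10.1% of runs), which leaves this part open. At 37 to 60 Mb, which holds Trem2 but not Hspa1a and Hspa1b, the shares without Trem2 were 23.5% of 115 genes (percentile 99.7; 2.45% of runs) and 23.7% of 114 (percentile 99.8), and an effect of losing Trem2 stays open and untested.

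For the height of the MHC class I and II genes, an interferon response would raise other interferon genes. The 49 measured members of both interferon lists outside the MHC had a median of -0.47 relative to all genes (bootstrap interval -0.90 to -0.26). Most of these belong to the type I list. The interferon-gamma list alone was at -0.18 and percentile 14.8, but it includes Tap1, Tap2, Psmb8 and Psmb9 of the MHC region. These lay 0.40 to 2.09 above all genes. Most of the list's other measured members lay below all genes, such as Irgm2 (-1.38), Iigp1 (-1.06) and Gbp2 (-0.90). Irf8, Irf1 and Serping1 lay above (0.47, 0.88 and 0.89), and like Tap2, Psmb8 and Psmb9 were named after their values were seen. The list was not tested without its MHC genes, so a response to interferon-gamma is not decided. B cells would bring their receptor chains Cd79a and Cd79b, but these, chosen after their values were seen, were at 0.351 and 0.708 FPKM and at 0.652 and 0.614 FPKM, in the knockout together 1.59% (counting limit 2.37%) of the 83.2 FPKM that H2-Aa gained, which argues against B cells. A direct effect of the chromosome 17 stretch on the genes it holds is not the whole of it. The measured MHC list members on other chromosomes, Cd74 and B2m, lay at least 1.66 above all genes on the log2 scale. The 8 listed B cell and dendritic cell markers had a median log2 fold change of 0.13, where the class II median was 3.57. Their highest was 0.79, or 1.10 relative to all genes, that of Bst2 (125 and 217 FPKM). As a plain ratio Ccl22, also among the 8, was highest at 4.16-fold, though low (0.184 and 0.765 FPKM). Only 5 of the 14 dendritic cell markers were listed, and genes low in both libraries are not in the data. Itgax, a marker of dendritic cells and some macrophages, chosen after its values were seen, was at 10.02 and 27.1 FPKM. Dendritic cells stay open, since low markers cannot exclude a small share of them. Effects of the stretch on part of the genes, and of losing Trem2, may both remain and were not separated.

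For the height of contractile and matrix genes, removing the trends with GC content and length left the list at percentile 100, which argues against these as the cause. A larger share of fibroblasts in the knockout culture cannot be told apart from a change within cells by the 5 fibroblast markers outside the matrix list. These had a median of 0.44 relative to all genes, under the 0.81 of the matrix list, but with a bootstrap interval from -1.81 to 2.15. Pdgfra (29.3 and 6.0 FPKM) and Thy1 (0.336 and 3.80 FPKM) went opposite ways among them. Of all 10 fibroblast and pericyte markers 3 were at least 2-fold higher and 2 lower as deposited. Dcn, named after its values were seen, was at 71.4 and 48.9 FPKM, and Col1a2 at 50.6 and 108 FPKM, where Tagln was 49.0-fold higher. A larger share alone, raising all fibroblast markers alike, would not give these values. An effect of losing Trem2 on the contractile and matrix genes stays open and untested.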
